A study of Homo sapiens with 6 samples.

How the data were processed

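RNA was profiled in PANC-1, an established human pancreatic cancer cell line, in 3 untreated samples and in 3 samples exposed for 2 weeks to extracellular vesicles (EVs) from cancer-associated fibroblasts (CAFs). Per the labels' protocols, ribosomal RNA was depleted from 1 µg of total RNA, and libraries were made with a kit that incorporates uracil into the second cDNA strand and removes that strand, so the reads keep their strand. Paired reads of 150 bases were sequenced. The protocol text that mentions the vesicles is repeated for every sample, and the groups were taken from the sample titles, which the treatment labels match. The headings of the count columns begin with NCP for the untreated samples and coP for CAF-EV replicates 1 and 2. That of CAF-EV replicate 3 begins with lnc_pan, and no reason is given. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

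The authors deposited 1 table of whole-number counts for 127365 lncRNA transcripts, of which 42368 carry an Ensembl identifier and 84997 are assembled transcripts named by the authors as lncRNA. TopHat and the hg19 build are named in the submitters' processing notes; the counting tool, its strand setting and the rule for sharing reads between overlapping transcripts are not given in the sources used here. Counts of overlapping genes on opposite strands are therefore uncertain. The coordinates in the table are those of GRCh38 rather than hg19. Of 18691 transcript identifiers with the same version in GENCODE v29 (GRCh38), 100.0% shared a start or an end with that annotation and 48.6% shared both. Coordinates below are as the table gives them. The value 1 never occurred, and the smallest value above 0 was 2, which no stated step accounts for. The table holds no protein-coding genes, so the comparison planned for them was not made. An assembled transcript may carry the name of a protein-coding gene that it overlaps, and its count is not the expression of that gene.

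Transcript counts were summed over each pair of locus and gene name, giving 68585 genes. Of these, 12786 hold at least 1 Ensembl transcript and are called reference genes here. Whether a read was counted on more than 1 transcript is not known, so the sum of a gene may count a read repeatedly. Total counts ranged from 10727165 to 17342985 per library. The main test was edgeR's quasi-likelihood F test over all 6 libraries, with robust dispersion, TMM factors and edgeR's default filter. Benjamini-Hochberg adjustment was used at 0.05. The standard errors (SE) given with edgeR's log2 fold changes are not estimates of the model. Each was calculated back as the absolute log2 fold change over the square root of the F statistic. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 5 tested members, again with Benjamini-Hochberg adjustment over the lists. Of 32 lists fixed before the data were examined, 28 had no member in the table, and the list of small structured RNAs had 1 member. The 3 tested were cancer-associated lncRNAs, snoRNA host lncRNAs and miRNA host lncRNAs. The cancer-associated list shares SNHG1, GAS5 and DANCR with the snoRNA host list. It shares H19, MEG3, MIR31HG and DLEU2 with the miRNA host list, so the list results are not independent. Library composition was compared with two-sided exact permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

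Genes were named by a rule fixed before the data were examined: up to 12 genes higher and 12 lower past the threshold with non-overlapping groups and a mean CPM of at least 1, up to 4 members with the smallest p of each list discussed, and, if no gene passes, the 5 with the smallest p. XIST and Y-linked genes were left out. CPM here are raw counts scaled by the library total, without TMM factors. Intervals were not given for single counts, since reads without molecular identifiers are not independent molecules. A fold over libraries that are all at 0 is a lower bound against a floor of 3 counts over the untreated libraries compared.

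The alternatives planned were other scaling factors, other filters, DESeq2, limma voom with sample quality weights, a replicate block, leaving out each library, a fold threshold, the reference genes alone, and other list tests. Added after the data were seen were the highest-count transcript per gene, scaling on the 200 most abundant reference genes, and a comparison of 2 untreated with 2 treated libraries that leaves out untreated replicate 2 and CAF-EV replicate 3. For that comparison 5 filters were tried. A minimum mean CPM of 10 is the one described in most detail, and it was chosen after all 5 had been run, of which the default filter and a minimum of 1 gave no calls. The named genes of that comparison follow the same rule, restricted to reference genes.

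The code was tested on simulated counts with 200 changed genes, 50 at each of 4-fold, 16-fold, 64-fold and 256-fold. For the 6 libraries, with the dispersions fitted to each gene, 0 of 50 genes were recovered at each of these sizes over 54604 simulated genes. With a dispersion of 0.05 in their place, 45 of 50 were recovered at 4-fold and 50 of 50 at each larger size. For the 2 untreated and 2 treated libraries, over 4032 simulated genes, 46 of 50 were recovered at 4-fold, 50 at 16-fold, 49 at 64-fold and 49 at 256-fold, with 16 unchanged genes called.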

Results

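The series profiled lncRNA in PANC-1 pancreatic cancer cells and compared 3 untreated libraries with 3 libraries from cells treated for 2 weeks with EVs secreted by CAFs, the fibroblasts of the tumour stroma. The comparison addresses which lncRNAs differ after CAF-EV treatment. Total counts were 17279286, 17167919 and 17342985 in untreated replicates 1, 2 and 3, and 10727165, 13865747 and 14179719 in CAF-EV replicates 1, 2 and 3.

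MALAT1, an abundant nuclear lncRNA at chromosome 11, 65497688 to 65507432 on the plus strand of GRCh38, had 1438040, 3079724 and 1340829 counts over its 17 listed transcripts in untreated replicates 1, 2 and 3. It had 7805 and 235439 counts in CAF-EV replicates 1 and 2. In CAF-EV replicate 3 it had 1293 counts, whereas TALAM1, the antisense transcript of the same locus (65499312 to 65508336, minus strand), had 1438303. TALAM1 had between 234 and 1034 counts in the other 5 libraries. VIM-AS1, antisense to the vimentin gene (chromosome 10, 17214239 to 17230018), had 103689 counts on its most counted transcript in CAF-EV replicate 3 and 22 to 131 in the others. Of the counts on assembled transcripts named for a protein-coding gene, 99.8% lay on the strand opposite to that gene in CAF-EV replicate 3. The same share was 67.9%, 71.2% and 67.6% in untreated replicates 1, 2 and 3, and 68.5% and 68.3% in CAF-EV replicates 1 and 2.

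**Figure D1:**
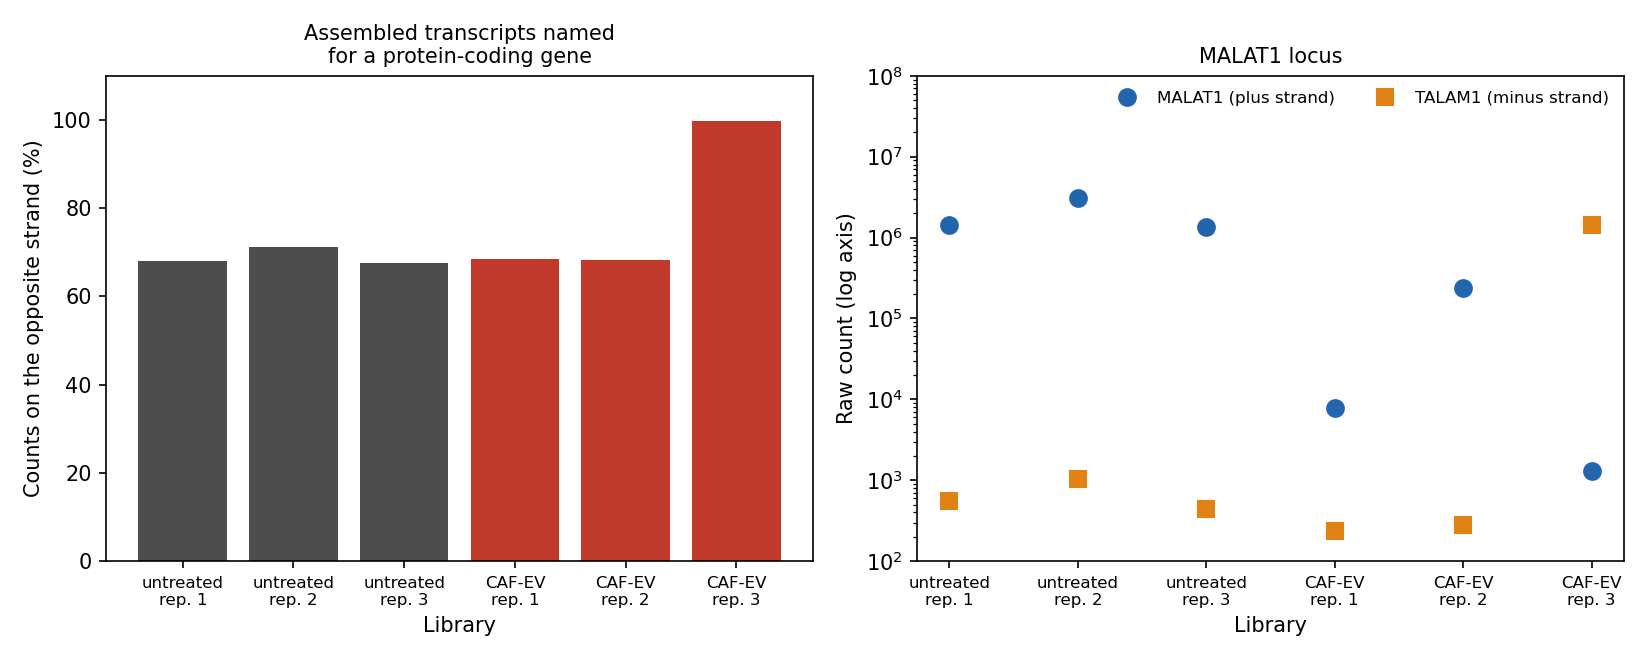
Left, bars give the percent of counts on the opposite strand for assembled transcripts named for a protein-coding gene, in each of the 6 libraries. Right, points give raw counts of MALAT1 (circles) and TALAM1 (squares) on a log axis; in CAF-EV replicate 3 TALAM1 stands at 1438303 and MALAT1 at 1293, the reverse of the order in the other 5 libraries.

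The libraries of a group differed in other ways. The share of transcripts at 0 was 16.7%, 71.2% and 16.2% in untreated replicates 1, 2 and 3, and 3.37%, 3.29% and 69.2% in CAF-EV replicates 1, 2 and 3. Transcripts of the mitochondrial chromosome took 13.04%, 39.4% and 20.1% of the untreated counts and 5.05%, 7.07% and 11.1% of the treated counts. The group means of this share were 24.2% ± 13.6 (SD, n = 3) and 7.73% ± 3.06 (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allow, and an adjusted p of 0.267 over 8 measures of composition. The total count, 17263397 ± 88608 against 12924210 ± 1909162 (SD, n = 3 each), gave the same exact p of 0.1. Across reference genes, the Pearson correlation of log2 CPM was 0.88 between untreated replicates 1 and 3 and 0.92 between CAF-EV replicates 1 and 2. Between untreated replicates 1 and 3 and CAF-EV replicates 1 and 2 it was 0.83 to 0.84. Untreated replicate 2 lay further away, at 0.70 and 0.71 with untreated replicates 1 and 3. The correlation of untreated replicate 2 with CAF-EV replicates 1 and 2 was 0.67 and 0.68. For CAF-EV replicate 3 with each of the other libraries it lay between -0.03 and 0.05.

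No gene passed the threshold between the 3 treated and the 3 untreated libraries. The 5 genes with the smallest p were 0 in every untreated library and had most of their counts in CAF-EV replicate 3. They were an assembled transcript within the MTPN locus (chromosome 7, 135927573 to 135930569), ENSG00000279605, ENSG00000289100, ICAM4-AS1 (antisense to the blood group gene ICAM4) and ENSG00000280195. The MTPN-named transcript had 5.13, 5.70 and 1150 CPM in CAF-EV replicates 1, 2 and 3, and its treated mean was at least 6677-fold above the floor of 3 counts over the 3 untreated libraries. Without CAF-EV replicate 3 it was at least 93.4-fold above that floor. ICAM4-AS1 (chromosome 19, 10285801 to 10289019) had 5.97, 4.83 and 609 CPM, with a treated mean at least 3568-fold above that floor, and at least 93.2-fold without CAF-EV replicate 3. Neither passed in edgeR's quasi-likelihood test, with an adjusted p of 0.742 for each. Over 54604 tested genes, edgeR called 0, with 1055 at an unadjusted p under 0.05, 1043 higher and 12 lower in the treated group. Of the 1043, 367 had over 90% of their treated counts in CAF-EV replicate 3. Of the 12149 tested reference genes, 0 were called and 491 had an unadjusted p under 0.05. Among all tested genes and among reference genes, the share at an unadjusted p under 0.05 was below 0.05, the share expected without any change. DESeq2 called 345 genes higher and 12 lower, and limma voom with sample quality weights called 1132 higher and 221 lower while giving weights of 0.0732 to untreated replicate 2 and 0.0404 to CAF-EV replicate 3. The common dispersion of the 6 libraries was 2.45.

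The list of snoRNA host lncRNAs is meant for genes whose introns encode small nucleolar RNAs. Whether each member, such as CCDC26, does so was not checked. Fitted values were lower in the treated group for 28 of 29 tested members, with a median log2 fold change of -2.46. No member passed over all genes, and 0 passed when adjusted over the list alone. camera gave an adjusted p of 1.8e-27 for the list, with an adjusted p of 0.154 with an estimated correlation. SNHG5 (chromosome 6, 85650491 to 85678932) had 9772 ± 4137 CPM in untreated and 301 ± 267 in treated libraries (SD, n = 3 each), and SNHG29 (chromosome 17, 16438767 to 16480249) had 5425 ± 1819 and 211 ± 161. SNHG6 and SNHG25 were the other members with the smallest p, at log2 fold changes of -5.06 (SE 2.84) and -4.65 (SE 2.65), with an adjusted p of 1.00 in edgeR for each. The treated values include CAF-EV replicate 3, in which SNHG5 had 3.95 CPM and SNHG1, SNHG4 and SNHG11 had 0 counts. SNHG4, SNHG14 and CCDC26 are among the 28, at log2 fold changes of -0.88, -0.73 and -0.25. Without CAF-EV replicate 3 and untreated replicate 2 they were at 0.32, 0.10 and 0.25, and 21 of 24 tested members had lower fitted values. CAF-EV replicate 3 also enters the direction counts of the lists below.

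The cancer-associated lncRNAs had lower fitted values for 33 of 43 tested members, with a median log2 fold change of -0.53. None passed over all genes and 1, THRIL, passed when adjusted over the list alone. The camera adjusted p was 2.1e-10, and the adjusted p was 0.154 with an estimated correlation. THRIL was 0 in the untreated libraries and had 2.98, 5.05 and 124 CPM in CAF-EV replicates 1, 2 and 3. H19, an imprinted lncRNA (chromosome 11, 1995166 to 2001470), had 2537 ± 1389 CPM in untreated and 121 ± 64.4 in treated libraries, and NORAD (chromosome 20, 36045618 to 36051018), a cytoplasmic lncRNA that binds Pumilio proteins, had 241 ± 158 and 9.49 ± 8.93 (SD, n = 3 each). VIM-AS1 had a log2 fold change of 8.11 (SE 3.35), which was -1.81 without CAF-EV replicate 3. The miRNA host lncRNAs had lower fitted values for 17 of 29 tested members, a median log2 fold change of -0.34 and a camera adjusted p of 9.3e-04, with an adjusted p of 0.294 with an estimated correlation. None of them passed over all genes or when adjusted over the list alone. Without untreated replicate 2 the camera adjusted p of this list was 0.0905. MIR497HG, H19, MIR4435-2HG and MIR22HG had its smallest p, with log2 fold changes of 6.09 (SE 2.85), -5.23 (SE 2.93), -2.37 (SE 2.54) and -2.25 (SE 2.46). MIR497HG had 83, 20 and 2342 counts in CAF-EV replicates 1, 2 and 3, and its log2 fold change was 2.26 without CAF-EV replicate 3. Without untreated replicate 2, those of MIR4435-2HG and MIR22HG were -1.22 and -1.43. The 1 tested small structured RNA, TERC, the RNA template of telomerase, had a log2 fold change of -2.01 (SE 2.29).

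A comparison of untreated replicates 1 and 3 with CAF-EV replicates 1 and 2 was chosen after the data were seen. At a minimum mean CPM of 10, edgeR's quasi-likelihood test called 14 genes higher and 137 lower among 4032. Among the 2676 tested reference genes it called 5 higher and 134 lower. The count depends on the filter. It was 47 higher and 135 lower at a minimum of 5, 6 and 81 at a minimum of 50, and 0 at a minimum of 1 and with the default filter, where 2429 and 4264 genes had an unadjusted p under 0.05. DESeq2 called 57 higher and 241 lower on the same 4032 genes, and 1051 and 243 on every gene with a count. With untreated replicate 2 put back, edgeR called 0, with 207 at an unadjusted p under 0.05. With library totals alone, which move the median log2 fold change of all genes from 0.02 to 0.39, 67 were higher and 113 lower. Scaling on the 200 most abundant reference genes, which moves it to 0.32, gave 42 and 110. Without untreated replicate 1 the counts were 45 higher and 97 lower, without untreated replicate 3 they were 48 and 89, without CAF-EV replicate 1 they were 9 and 138, and without CAF-EV replicate 2 they were 15 and 175. In these fits the single library left in a group is assumed to vary like the others.

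Other measures differed between these 4 libraries as well. The mitochondrial share was 13.04% and 20.1% in untreated replicates 1 and 3 against 5.05% and 7.07% in CAF-EV replicates 1 and 2. In 19 overlapping gene pairs chosen for a clear strand in the untreated libraries, the median log2 ratio of the usual over the other strand was 7.06 and 6.13 against 1.91 and 2.71. Choosing pairs by their untreated ratio by itself favours lower ratios in the treated libraries. How much of this difference is due to that choice is not known. In these 4 libraries, 14 of 24 tested snoRNA host lncRNAs fell and none rose over all genes, and 17 passed when adjusted over the list alone, all of them lower. Over all genes, 8 fell without untreated replicate 1 and 9 without untreated replicate 3. The list's median log2 fold change was -1.65. Relative to the median of all genes it was -1.67, also with RLE factors, library totals and scaling on the 200 most abundant reference genes. These values are alike by construction, since a scaling shifts the list and all genes together. Falls also occurred outside this list, but at a smaller share: of all 2676 tested reference genes, 134 fell. At a minimum mean CPM of 50, 12 of 19 list members fell, against 78 of 619 reference genes. camera gave an adjusted p of 7.7e-33, and the adjusted p was 0.0398 with an estimated correlation. SNHG5 fell by 4.34 on the log2 scale (SE 0.25, edgeR adjusted p 0.00295), SNHG29 by 4.25 (SE 0.50, adjusted p 0.0362), and SNHG16, which was chosen after its values were seen, fell by 3.03 (SE 0.16). SNHG29 did not pass without untreated replicate 1 or 3, at log2 fold changes of -4.33 and -4.16, or at a minimum mean CPM of 5, at -4.27. Of 37 tested cancer-associated lncRNAs, 8 fell and none rose over all genes, with SNHG1 and GAS5 of the snoRNA host list among them. When adjusted over the list alone, 13 passed, all lower. Over all genes, 6 fell without untreated replicate 1 and 5 without untreated replicate 3. The list's median log2 fold change was -0.29, and -0.31 relative to the median of all genes. Library totals alone and scaling on the 200 most abundant reference genes moved all genes, so that the list's median was 0.08 and 0.01, and left it at -0.31 relative to all genes. The camera adjusted p was 5.4e-10, and 0.0398 with an estimated correlation. H19 fell by 3.79 (SE 0.26, edgeR adjusted p 0.00336) and NORAD fell by 3.68 (SE 0.30, adjusted p 0.00493). NEAT1, the scaffold of paraspeckles, and PVT1, a neighbour of MYC, both chosen after their values were seen, had log2 fold changes of -2.71 (SE 0.30) and -1.58 (SE 0.17) and passed. MALAT1 had a log2 fold change of -3.45 with an SE of 1.79 and did not pass (adjusted p 0.652). Of 20 tested miRNA host lncRNAs 2 fell, H19 and MIR4435-2HG, the second by 0.84 (SE 0.14), and the camera adjusted p of 0.0228 became an adjusted p of 0.205 with an estimated correlation. H19 alone was called with library totals, with scaling on the 200 most abundant reference genes, and without untreated replicate 1 or 3. The camera adjusted p was 0.0572 with library totals and 0.198 at a minimum mean CPM of 50. It was 0.157 without untreated replicate 3, 0.0736 without CAF-EV replicate 2 and 0.00344 without CAF-EV replicate 1. The list's median was -0.27, and relative to all genes it was -0.29, both with TMM factors and with library totals, where the list's own median was 0.10.

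**Figure D2:**
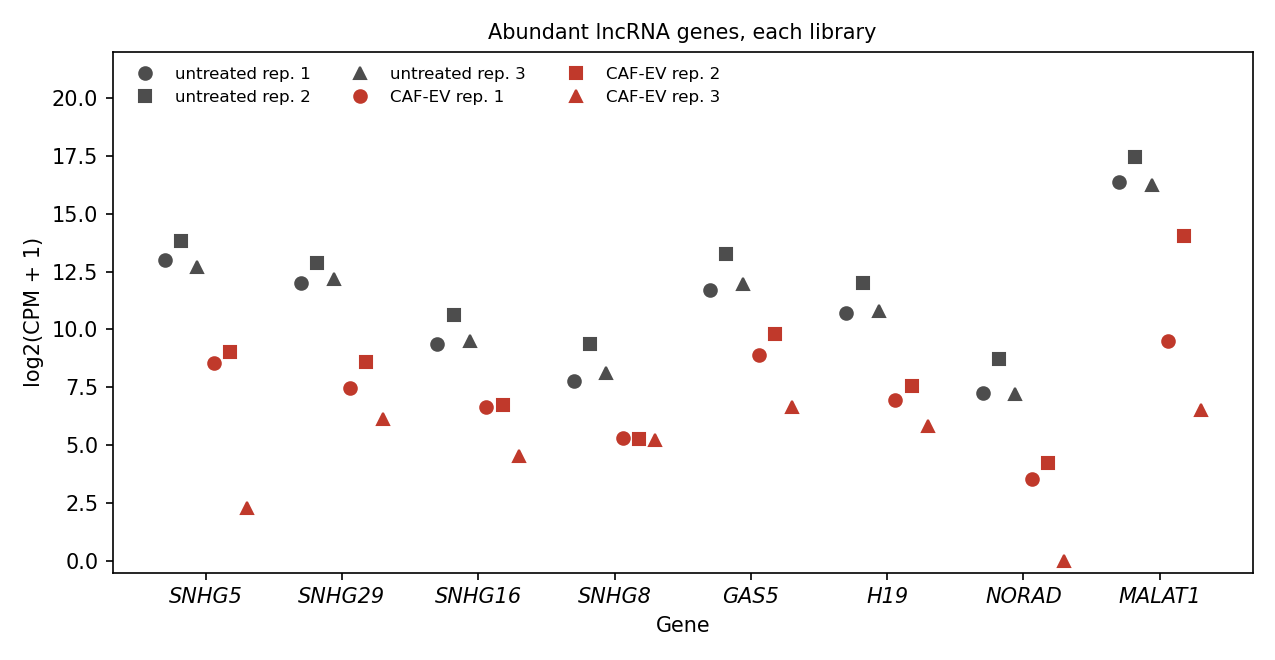
Points give log2(CPM + 1) of 8 abundant lncRNA genes in each library, grey for untreated and red for CAF-EV, with a marker shape per replicate number; the genes were chosen after their values were seen. For SNHG5 the untreated libraries lie at 8252, 14455 and 6610 CPM and the treated ones at 378, 521 and 3.95.

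Among the called reference genes, the others with the largest falls in these 4 libraries were ENSG00000257379, which fell by 5.22 on the log2 scale (SE 0.43), ENSG00000284707, by 5.00 (SE 0.21), and ENSG00000285338, by 3.71 (SE 0.35). EXO5-DT (chromosome 1, 40493157 to 40508718), a divergent transcript of the exonuclease gene EXO5, fell by 3.52 (SE 0.31), and ENSG00000267009, ENSG00000284829, ENSG00000272639 and ENSG00000235288 fell by 3.30 to 3.39. Of these, ENSG00000272639 did not pass without untreated replicate 3, at a log2 fold change of -3.06. Only 4 named reference genes met the rule for a rise. ENSG00000279159 (chromosome 22, 29978950 to 30028236) was 0 in the untreated libraries and had 67.5 and 59.5 CPM in CAF-EV replicates 1 and 2, at least 733-fold above a floor of 3 counts over untreated replicates 1 and 3. UBAC2-AS1, ENSG00000266469 and FAM13A-AS1 rose by 1.83 (SE 0.27), 1.30 (SE 0.23) and 1.03 (SE 0.18) on the log2 scale in edgeR. UBAC2-AS1 did not pass without untreated replicate 3, CAF-EV replicate 1 or CAF-EV replicate 2, at log2 fold changes of 1.62, 1.74 and 1.90. ENSG00000266469 and FAM13A-AS1 did not pass without any 1 of the 4 libraries, at 1.25 to 1.36 and 0.96 to 1.10, or at a minimum mean CPM of 5, at 1.28 and 1.00.

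Abundant genes were grouped by their ratio in untreated replicate 2. Of 295 reference genes with a mean of at least 1500 counts in untreated replicates 1 and 3, 52 had at least a 2-fold higher count in untreated replicate 2. Their median ratio to the mean of untreated replicates 1 and 3 was 0.0811 in CAF-EV replicate 1 and 0.185 in CAF-EV replicate 2, and the ratio was under 0.5 for 52 and 50 of them. The 105 genes with a ratio of 0.5 or less in untreated replicate 2 had median ratios of 0.826 and 0.971, with 1 and 0 under 0.5. The 138 genes between had median ratios of 0.586 and 0.729, with 48 and 33 under 0.5. Among these were SNHG5, at 0.0316 and 0.0561, and SNHG29, at 0.0251 and 0.0705. For 2 treated libraries these are values of the libraries, with no test.

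**Figure D3:**
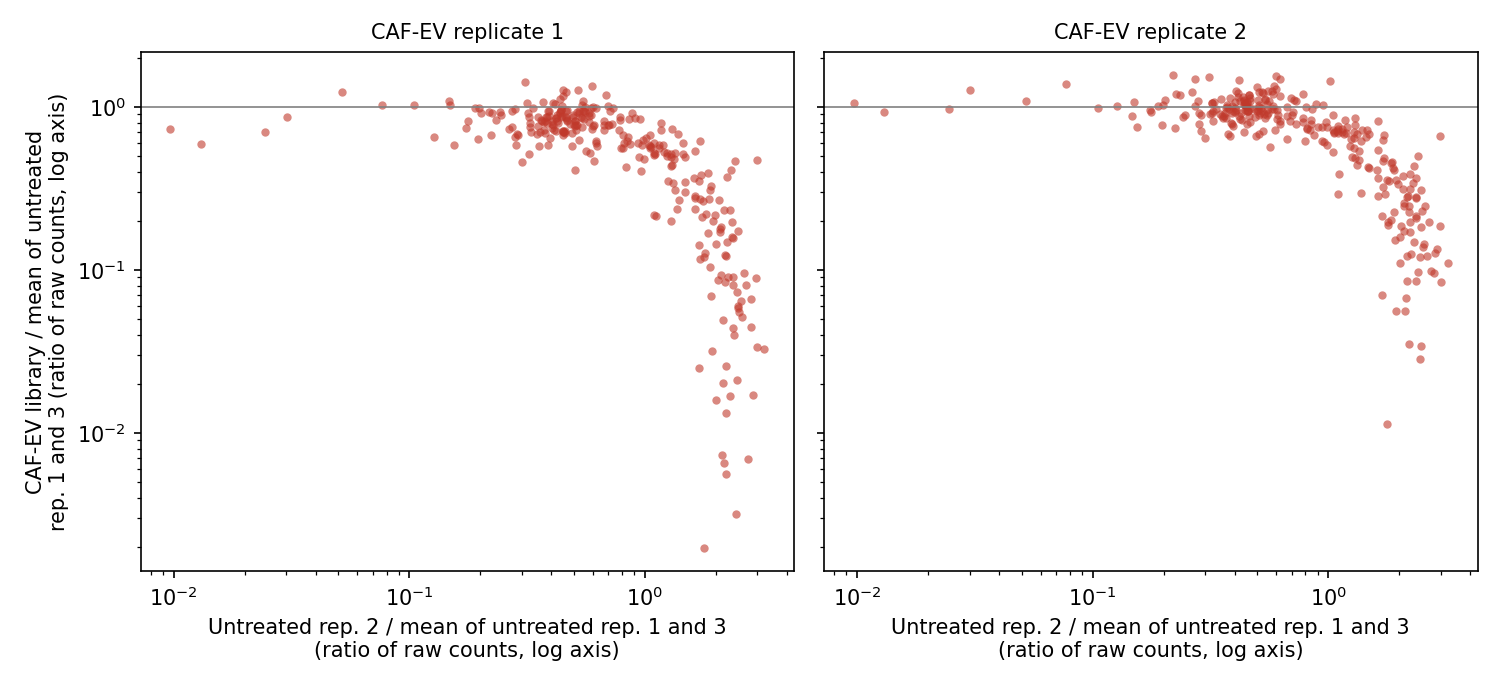
Each point is 1 of 293 reference genes with a ratio above 0; the horizontal axis gives the count in untreated replicate 2 over the mean of untreated replicates 1 and 3, and the vertical axis the count in CAF-EV replicate 1 (left) or 2 (right) over the same mean, both on log axes. Genes with a horizontal ratio of at least 2 have median vertical ratios of 0.0811 and 0.185.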

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

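The alternatives on 2 untreated and 2 treated libraries, on the highest-count transcript and on the 200 most abundant reference genes were chosen after the data were seen. edgeR called 0 genes in each direction, among all genes and among reference genes, with RLE factors, library totals, without mitochondrial and small structured RNAs, without a filter, with a CPM of at least 1 in at least 3 libraries, with the reference genes alone, with a log2 fold change of at least 1, and without each library in turn (0 to 0). Upper-quartile factors could not be computed, because the upper quartile of a library was 0, and the protein-coding result has no alternative. DESeq2 gave 345 genes higher and 12 lower (reference genes 176 and 12), and limma voom with quality weights 1132 and 221 (244 and 167); the cause was not tested. The number of lists called by camera was 3, it was 2 to 3 without each library, and 0 with an estimated correlation and 0 with fry, neither of which assumes the preset correlation. The replicate numbers did not pair the libraries: the correlations of same-numbered deviations were 0.06, -0.09 and -0.06. With a replicate block edgeR called 0 genes, with 209 at an unadjusted p under 0.05, and 3 lists. VIM-AS1 changed sign from 8.11 to -0.88 with limma voom, -0.47 with the replicate block, -1.81 without CAF-EV replicate 3 (the range without each library was -1.81 to 8.91) and -1.03 with untreated replicate 2 left out too. MIR4435-2HG changed sign to 0.84 with the highest-count transcript.

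For the 2 untreated and 2 treated libraries, against 14 genes higher and 137 lower (reference genes 5 and 134), the counts were 67 higher with library totals (37), 42 with scaling on abundant reference genes (21), 47 at a minimum mean CPM of 5 (22), 6 and 81 at a minimum of 50 (3 and 78), 57 and 241 with DESeq2 (26 and 223) and 1051 and 243 with DESeq2 on every gene with a count (287 and 217). They were 0 and 0 (0 and 0) at a minimum of 1, with edgeR's default filter, and with untreated replicate 2 added. Leaving out each of the 4 libraries gave 9 to 48 higher and 89 to 175 lower (2 to 9 and 85 to 161). The default filter and a minimum of 1 test more genes, 61289 and 46182. Whether this accounts for their 0 calls was not tested, and neither was the cause of the other moves. Of the 151 calls, 151 were shared with DESeq2 on the same genes, 123 with library totals, 124 with scaling on abundant reference genes, 122 and 69 at a minimum mean CPM of 5 and 50, and 93 to 130 without each library (100 and 93 without untreated replicates 1 and 3); 0 were shared at a minimum of 1, with the default filter, or with untreated replicate 2 added. For the 16 genes named from these libraries, 151 alternative values kept direction and call, 63 kept the direction and lost the call, and 0 reversed. In simulated data the depth of 10727165 to 17342985 counts did not by itself limit the 6-library test. At these depths, the dispersions fitted to each gene left 0 of 50 genes recovered at 256-fold, and a dispersion of 0.05 gave 50 of 50. Depth itself was not varied.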

Other observations

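All tests in this part except the counts of splits were chosen after the result was seen. The thresholds of the strand and abundance tests were also set then.

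The MALAT1 locus, both strands together, took 8.33%, 17.9% and 7.73% of counts in untreated replicates 1, 2 and 3, and 0.0749%, 1.70% and 10.2% in CAF-EV replicates 1, 2 and 3. A total of 40 genes were exactly 0 in untreated replicates 1 and 3 with at least 100 counts in CAF-EV replicates 1 and 2, and 1 gene showed the opposite. Neither of the mixed pairings of these 4 libraries gave any such gene (0 and 0). An unnamed locus at chromosome 16, 46380683 to 46421813, took 8.84%, 3.91% and 7.50% of the untreated counts and 12.5%, 12.0% and 0% of the treated counts.

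CAF-EV replicate 3 held its counts on the strand opposite to the other libraries. Of 19 overlapping reference gene pairs with a clear usual strand in the untreated libraries, the other strand was higher in 14 (73.7%) in CAF-EV replicate 3 and in 0 or 1 elsewhere. The median log2 ratio of the usual over the other strand in these pairs was 7.06, 10.94 and 6.13 in untreated replicates 1, 2 and 3, and 1.91, 2.71 and -2.92 in CAF-EV replicates 1, 2 and 3. The untreated values are favoured by the choice of pairs, so they are no yardstick for the treated ones. CAF-EV replicates 1 and 2 were not used in the choice and had 1 reversed pair each, against 14 in CAF-EV replicate 3. The pairs were picked after a weaker first look at all 1002 pairs. There the strand ratios of CAF-EV replicate 3 had a Pearson correlation of -0.15 to 0.01 with the other libraries. Among themselves the other libraries had 0.63 to 0.84. A candidate explanation is that CAF-EV replicate 3 was counted with the opposite strand setting, which the strand-keeping kit allows. The heading of its count column also differs in kind from those of CAF-EV replicates 1 and 2. Whether it was made together with them is not stated. Antisense transcription raised by the treatment would not account for the 99.8% in CAF-EV replicate 3, since CAF-EV replicates 1 and 2 had the same treatment and were at 68.5% and 68.3%. These lay under the 71.2% of untreated replicate 2 and above the 67.9% and 67.6% of untreated replicates 1 and 3, so a small rise in them is not excluded.

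The 52 abundant reference genes at least 2-fold higher in untreated replicate 2 were lower in CAF-EV replicates 1 and 2. The lower total counts do not account for these 52: the library totals were 0.620 and 0.801 of the mean of untreated replicates 1 and 3, and the higher of their median ratios was 0.185. The median ratios of the other abundant genes were 0.826 and 0.971 for 105 of them and 0.586 and 0.729 for 138. Of these 138, 48 and 33 had ratios under 0.5, among them SNHG5 (0.0316 and 0.0561) and SNHG29 (0.0251 and 0.0705), whose ratios the lower totals do not account for either. Assembled transcripts named for a coding gene had median counts on the opposite and the same strand of 16 and 17 in untreated replicates 1 and 3, 14 and 14 in CAF-EV replicate 1, and 17 and 17 in CAF-EV replicate 2. These are the 4 libraries compared without the other 2, which had 0 and 0 (untreated replicate 2) and 8 and 0 (CAF-EV replicate 3). Another candidate is less RNA over a background without strand. Such a mixture in each library predicts a straight line between both libraries' ratios. Over the 52 genes the SD of log2 ratios fell from 0.97 to 0.546 around that line, against 0.260 from the untreated pair and counting. The residual was 2.10 times the latter, close to the limit of 2 set after the data were seen, and 12 genes lay beyond 2 expected SD. The yardstick is the spread of 1 untreated pair. The mixture may therefore account for part, and whether it accounts for all is not settled. An effect of the treatment on these lncRNAs, SNHG5 and SNHG29 included, and library quality cannot be told apart here. At the MALAT1 locus CAF-EV replicate 3 took 10.2%, within the untreated range of summed transcripts. That share rests almost wholly on the 1 TALAM1 transcript, whereas the untreated shares sum 17 MALAT1 transcripts. On the most counted MALAT1 transcript alone the untreated libraries had 2.33%, 5.00% and 2.20%, against 10.1% on TALAM1. The 10.2% speaks against a shared fall only if CAF-EV replicate 3 was counted on the opposite strand. It also depends on how overlapping transcripts share reads, which is not given.

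With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 0 genes, and the highest of the other splits gave 0; all 10 gave as many. For reference genes the real value was 0 and the highest other 0, again in 10 of 10. For gene lists the real split gave 3 and the highest other 3, with 7 of the 10 splits as large.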
